A study of Homo sapiens with 18 samples.

How the data were processed

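RNA of HCC827, ER3 and T15-2 cells treated with erlotinib or DMSO was labelled with biotin and hybridised to Illumina human expression BeadChips, with 18 arrays in 6 groups of 3. Groups and replicate numbers were taken from the sample labels. The deposited table of non-normalized data holds for each probe a bead summary signal, an intensity on a linear scale without background subtraction, and a detection p-value, which is low for bright probes. BeadStudio is named in the submitters' processing notes, and its version is not given in the sources used here. A second deposited table holds the authors' processed intensity values. Their ranks on each array equal those of the signals and their distribution is the same on each array, with medians between 57.69 and 57.71, so they are quantile-normalized on a linear scale; the step that made them is not described in the sources used here. It held 48797 probes, 6 fewer than the signal table. No column of other samples was present.

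Signals were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3: a normal-exponential model with the mean and SD of negative controls inferred from the detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p below 0.05 on at least 3 of the 18 arrays were kept (19931 probes). Genes were named from the platform annotation, with symbols updated by gene identifier through the RefSeq table of assembly GRCh38.p14; 28093 probes had 1 symbol, 13 had several and 20697 had none, and 28054 identifiers matched. Of the kept probes 15759 had 1 symbol. The probe with the highest mean stood for its gene, which gave 11820 genes, 3071 of them with several kept probes. Probes of the same gene were called in opposite directions for at most 26 genes in any comparison. No coordinates are reported, since the files name no genome build.

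Between 15698 and 17869 probes were above background on an array. Within groups the log2 values of arrays correlated between 0.991 and 0.997 across genes, and no arrays were identical. Where no probe of a gene was above background on any array of a group, the fold is a bound: the mean of the bright group over the mean, per array of the dim group, of the higher of the gene's own value and the lowest detected value.

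A single limma model with 6 group means was fitted to all 18 arrays, and 8 contrasts were tested with eBayes: erlotinib against DMSO in each line, each pair of lines in DMSO, and the erlotinib response of each subline minus that of HCC827. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 per contrast. Gene lists fixed before the data were examined, 27 of which had at least 4 measured members, were tested with camera at a preset correlation of 0.01, adjusted over all lists and contrasts, and again with an estimated correlation. A list gene was counted as risen or fallen when called over all genes; counts adjusted over the list alone stand beside these where they differ. Overlaps of calls were set against n1 × n2 / N per direction. The contrasts share an estimate of the spread per gene, which by itself can raise overlaps, in the same and in opposite directions alike.

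The rule for named genes was also fixed before the data were examined. It took, per contrast, the 8 largest rises and 8 largest falls among called genes whose replicate values did not overlap between groups, up to 4 members of each list with the largest absolute change, and EGFR, ERBB2, ERBB3, MET, AXL, GAS6, VIM, CDH1, DUSP6, CCND1 and BCL2L11. Which of the genes within this rule the text describes was settled after their values were seen.

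The script was tested on simulated arrays with the means and spreads of the 11820 genes and 200 changed genes. For the HCC827 erlotinib comparison it recovered 100% of genes changed 4-fold, 100% of those changed 2-fold, 76% at 1.5-fold and 8% at 1.25-fold, and 5.33% of the calls were false. For the difference of response between ER3 and HCC827 it recovered 100% at 4-fold, 94% at 2-fold and 36% at 1.5-fold. In the list test, 1 shifted list was recovered in both contrasts that held it, with 0 false calls among 216 tests. Genes were simulated independently of each other, so this does not test false list calls that come from correlation between genes.

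The alternatives were no background correction with a floor of 16, median scaling, the authors' processed values, no filter on dim probes, a filter at a detection p of 0.01 on all 3 arrays of a group, the mean of a gene's probes, a fit of the compared groups alone, eBayes with trend and robust settings, the replicate number as a block, a 2-fold minimum and leaving out each array in turn. The BeadChip as a block was not run, since no source used here gives the chip of each array. After seeing the data, fits without both arrays at the ends of the first component of the within-group spread, and with each array's score on that component as a covariate, were added. The covariate was used in 2 forms. The first took scores centred within each group, which cannot move a difference between groups, so a test of such a difference with it was void. The second, which projects each whole profile on the component, was chosen after the counts of the first had been seen, and both are reported. Figures were drawn with matplotlib 3.10.9.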

Results

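Gene expression was measured in HCC827, an EGFR-mutant line of non-small cell lung cancer, and in ER3 and T15-2, 2 sublines derived from it that resist erlotinib, an inhibitor of the EGFR tyrosine kinase. Each of the 3 lines was starved overnight and then kept for 12 h with 1 µM erlotinib or with DMSO, its solvent. Each of the 6 groups held 3 samples, and each sample was measured on 1 Illumina BeadChip array, 18 arrays in all. Between 15698 and 17869 of the 48803 probes lay above background on an array at a detection p below 0.05, and 11820 genes were tested. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values below measure only the spread between these samples. Changes are given as log2 values ± standard error (SE) from a limma fit over the 18 arrays, with n = 3 arrays per group, and adjusted p is limma's after Benjamini-Hochberg correction. List counts are of genes called over all genes tested, and where the count adjusted over the list alone differed it stands beside them. The number of arrays limits the precision.

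The first comparison asked what erlotinib changed in the sensitive parental line. FGFBP1, a secreted carrier protein for fibroblast growth factors, fell by 4.59 ± 0.10 on the log2 scale with erlotinib in HCC827 (adjusted p = 1.3e-16). ETV5, a transcription factor induced by ERK, changed by -4.31 ± 0.11, and the immediate early transcription factor EGR1 by -3.60 ± 0.14. CCND1, which encodes cyclin D1, changed by -3.18 ± 0.08, and FOSL1, a component of the AP-1 transcription factor, by -2.91 ± 0.13. DUSP6, the phosphatase that inactivates ERK, was not above background on any HCC827 array with erlotinib and was at least 12.4-fold lower than with DMSO (adjusted p = 7.9e-12). With erlotinib ETV5 and EGR1 were above background on 1 of 3 HCC827 arrays and FGFBP1 on 2 of 3. The largest rises were those of CYP1A1, a cytochrome P450 enzyme, by 3.06 ± 0.16, CHIA by 2.88 ± 0.11 and NUPR1 by 2.54 ± 0.14. PIK3IP1, a negative regulator of PI3 kinase, rose by 2.17 ± 0.09 and RGCC by 2.10 ± 0.11. The receptor gene MET changed by -1.71 ± 0.23 and ERBB3 by 1.36 ± 0.13, whereas EGFR (0.03 ± 0.11, adjusted p = 0.89) and AXL (-0.10 ± 0.17, adjusted p = 0.70) did not pass the test.

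**Figure D1:**
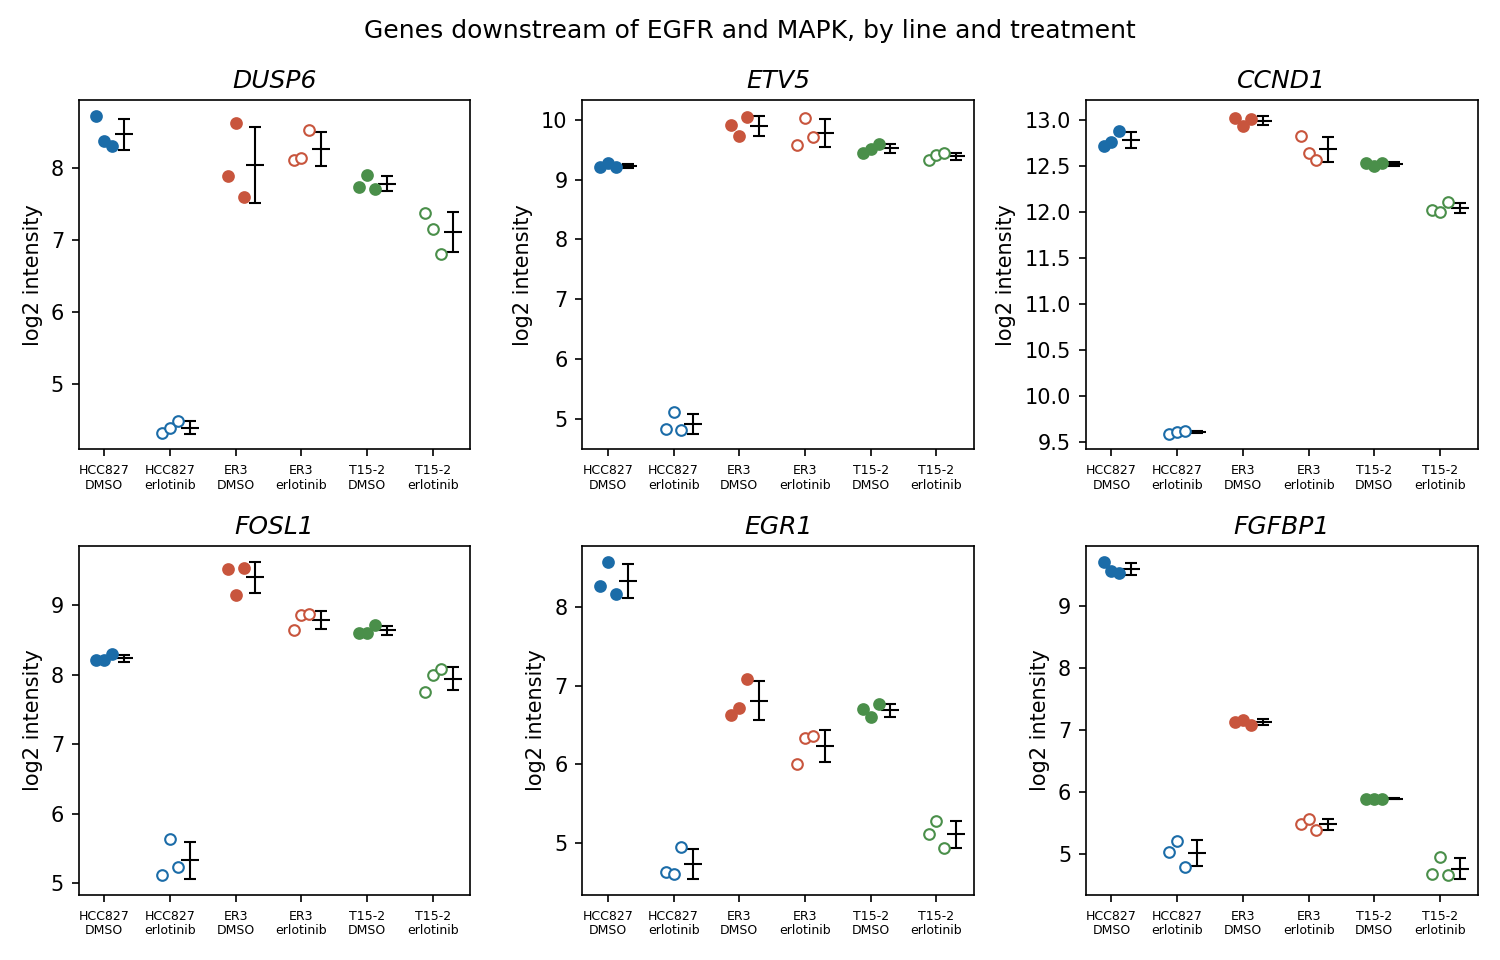
Log2 intensity (vertical axis, quantile-normalized) of 6 genes on each of the 18 arrays, by line and treatment (horizontal axis). Filled points are DMSO arrays, open points erlotinib arrays, and the bar beside each group is its mean ± SD (n = 3). In HCC827 the erlotinib arrays lie below the DMSO arrays for each of the 6 genes, by 4.31 log2 units for ETV5 and 3.18 for CCND1.

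Of 22 measured genes on the list of MAPK pathway output and feedback, 19 fell and 1 rose in HCC827 with erlotinib, with a median change of -1.31 (camera adjusted p = 1.5e-17). Of 31 genes for DNA replication and G1/S, 29 fell and none rose, among them MCM10 (-2.02 ± 0.15), UHRF1 (-1.90 ± 0.10), CDC45 (-1.72 ± 0.13) and the ribonucleotide reductase subunit RRM2 (-1.64 ± 0.14). The list of mitosis and G2/M genes was not called (9 of 33 fell, 4 rose, camera adjusted p = 0.75). Of 26 ribosome biogenesis genes, 23 fell and 1 rose, with RRS1 at -1.38 ± 0.08, PNO1 at -1.36 ± 0.14 and NOP56 at -1.30 ± 0.09 (24 fell and 2 rose adjusted over the list alone). Of 12 heat shock genes, 11 fell, led by the chaperone gene HSPA1A (-2.17 ± 0.08). Of 18 genes for cholesterol synthesis and uptake, 11 fell and 1 rose (12 fell adjusted over the list alone), and HMGCS1 changed by -1.04 ± 0.11. Of 21 glycolysis genes, 12 fell and none rose, including the glucose transporter SLC2A1 (-1.34 ± 0.09), but the call of that list was lost with an estimated correlation (adjusted p = 0.082 with an estimated correlation).

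Of 18 measured targets of FOXO transcription factors, 13 rose and none fell, with a median change of 0.58 (camera adjusted p = 7.6e-08); adjusted over the list alone 13 rose and 1 fell. YPEL3 rose by 1.81 ± 0.11, the repressor BCL6 by 1.68 ± 0.12 and KLHL24 by 1.60 ± 0.12. Of 14 cell cycle inhibitors and quiescence genes, 8 rose and 1 fell. CDKN1B, which encodes the inhibitor p27, rose by 1.04 ± 0.10 and CDKN1A, which encodes p21, fell by 1.09 ± 0.11 on the log2 scale. That list was called with the preset correlation and lost its call otherwise (adjusted p = 0.13 with an estimated correlation). Among BCL2 family genes, the pro-apoptotic BMF rose by 1.19 ± 0.13, BCL2L11, which encodes BIM, changed by 0.09 ± 0.15 (adjusted p = 0.68), and the list was not called. In all, 4458 of 11820 genes passed an adjusted p of 0.05, 2271 of them higher and 2187 lower with erlotinib, and 376 of these changed by at least 2-fold. Of the 27 lists, 12 were called in HCC827 with the preset correlation and 6 of these also with an estimated one.

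The same treatment in ER3 asked what remained of this response in a resistant subline. CYP1A1 was at least 3.14-fold higher with erlotinib in ER3, TCP11L2 (above background on 1 of 3 ER3 DMSO arrays) rose by 1.35 ± 0.12, CYP1B1 by 0.93 ± 0.12 and DDIT4L by 0.94 ± 0.10. PTGS2, which encodes the prostaglandin synthase COX-2, rose by 1.02 ± 0.10 (adjusted p = 4.2e-06). FGFBP1 fell by 1.65 ± 0.10 and HSPA1A by 1.04 ± 0.08 on the log2 scale. DUSP6 had a value of 0.22 ± 0.20 (adjusted p = 0.57), which was 0.52 (adjusted p = 0.040) in a fit without ER3 DMSO replicate 2 and T15-2 erlotinib replicate 3, chosen after seeing the data. CCND1 (-0.31 ± 0.08, adjusted p = 0.043), EGR1 (-0.57 ± 0.14, adjusted p = 0.030) and FOSL1 (-0.61 ± 0.13, adjusted p = 0.016) passed the test over 18 arrays. With the replicate number as a block CCND1 had an adjusted p of 0.062. The adjusted p-values of the 3 genes were 0.25, 0.15 and 0.12 in a fit of the ER3 arrays alone, and 0.11, 0.13 and 0.060 without ER3 DMSO replicate 3. The adjusted p of CCND1 was also 0.14, 0.092 and 0.13 without ER3 DMSO replicate 1, ER3 erlotinib replicate 2 and ER3 erlotinib replicate 3, that of EGR1 0.15 without ER3 erlotinib replicate 1, and that of FOSL1 0.073 and 0.080 without ER3 DMSO replicate 1 and ER3 erlotinib replicate 1.

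On the list of MAPK pathway output and feedback, 2 of 22 genes fell and 1 rose in ER3 (camera adjusted p = 0.90). Of the 31 DNA replication genes, 11 fell and none rose (20 fell adjusted over the list alone), with a median change of -0.29 (camera adjusted p = 4.3e-14) and FEN1, the flap endonuclease, at -0.67 ± 0.10. Of 12 heat shock genes 4 fell, and of 18 cholesterol genes 3 fell (7 and 7 adjusted over the list alone); both lists were called, with adjusted p = 0.00093 and 0.0026 with an estimated correlation. Of the 18 FOXO targets 6 rose and none fell (10 rose adjusted over the list alone), with KLHL24 at 0.66 ± 0.12 and YPEL3 at 0.69 ± 0.11. In a fit of the ER3 arrays alone the adjusted p was 0.063 for FEN1, 0.075 for KLHL24 and 0.095 for YPEL3. No ribosome biogenesis gene of 26 passed, and that list was not called (camera adjusted p = 0.19). In all, 444 genes passed in ER3, 238 higher and 206 lower, and 6 changed by at least 2-fold. This count rests on the spread pooled over 18 arrays: a fit of the 6 ER3 arrays alone called 14 genes, and 132, 242 and 150 genes were called without ER3 DMSO replicate 1, ER3 DMSO replicate 3 and ER3 erlotinib replicate 1. After median scaling in place of quantile normalization, 141 genes were higher and 228 lower.

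In T15-2, STC1, which encodes the glycoprotein stanniocalcin, changed by -1.75 ± 0.19 with erlotinib, EGR1 by -1.58 ± 0.14, ANGPTL4 by -1.44 ± 0.17 and FGFBP1 by -1.13 ± 0.10, and HSPA1A was 2.82-fold lower. FGFBP1 was above background on 1 of 3 T15-2 arrays with erlotinib, and CYP1A1 on 2 of 3 with DMSO. CYP1A1 rose by 1.20 ± 0.16, DDIT4L by 1.08 ± 0.10, BCO1 by 1.00 ± 0.10 and TXNIP, which encodes a thioredoxin inhibitor, by 1.00 ± 0.10. CCND1 changed by -0.48 ± 0.08 (adjusted p = 0.0014) and FOSL1 by -0.70 ± 0.13. DUSP6 changed by -0.67 ± 0.20 (adjusted p = 0.039), a call lost without T15-2 DMSO replicate 1, 2 or 3 (0.091, 0.12 and 0.071) and without T15-2 erlotinib replicate 2 or 3 (0.093 and 0.13), and on all arrays with no filter on dim probes (0.063). Of 31 DNA replication genes 26 fell and none rose (29 fell adjusted over the list alone), with a median of -0.61 (camera adjusted p = 1.5e-33), and UHRF1 and FEN1 changed by -1.05 ± 0.10 and -1.02 ± 0.10. Of 26 ribosome biogenesis genes 7 fell, of 12 heat shock genes 6 fell (11 and 9 adjusted over the list alone) and of 21 glycolysis genes 8 fell, among them the phosphofructokinase regulator PFKFB4 (-1.40 ± 0.13), and none of the 3 lists held a gene that rose. Of 18 FOXO targets 8 rose and none fell (10 rose adjusted over the list alone). On the MAPK list 3 of 22 genes fell and 1 rose (3 and 2 adjusted over the list alone, camera adjusted p = 0.084).

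Limma called 997 genes in T15-2, 524 higher and 473 lower (405 and 500 after median scaling), and 17 changed by at least 2-fold. The count lay between 441 and 1147 in fits without 1 array of T15-2; it was 511, 622 and 631 without T15-2 DMSO replicate 1, 2 and 3, and 441 and 524 without T15-2 erlotinib replicate 1 and 2.

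Whether a response differed between lines was tested directly, as the subline's erlotinib change minus that of HCC827. Both differences subtract the response of the same HCC827 arrays, so their agreement between the sublines is in part built in. A gene picked for a large change in HCC827 also tends to a large difference for that reason. ETV5 responded more weakly in both sublines, by 4.19 ± 0.16 in ER3 and 4.18 ± 0.16 in T15-2 (adjusted p = 2.0e-12 and 2.5e-12), with signal above background on 1 of 3 HCC827 erlotinib arrays. DUSP6 was below background on all 3 of those arrays, so its difference has only a lower bound, 3.85 in ER3 and 2.95 in T15-2. The difference for CCND1 was 2.87 ± 0.12 and 2.70 ± 0.12, and for the receptor gene MET 2.36 ± 0.32 and 2.08 ± 0.32. The rises of NUPR1 and RGCC in HCC827 were also smaller in the sublines, with differences of -2.11 ± 0.20 and -1.99 ± 0.15 in ER3 and -1.90 ± 0.20 and -2.06 ± 0.15 in T15-2, and that of CHIA in T15-2 (-2.14 ± 0.15). PTGS2 fell in HCC827 (-2.40 ± 0.10) and rose in ER3, and the difference was 3.42 ± 0.14. SGPP2 differed by 2.72 ± 0.16 in T15-2.

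Of the 22 genes of MAPK pathway output, 19 had a positive difference and 1 a negative one in ER3, with a median of 1.27, and 18 and 1 in T15-2, with a median of 1.29 (camera adjusted p = 8.2e-22 and 9.9e-26). The DNA replication list differed in the same direction in ER3 (26 of 31 genes) and in T15-2 (15 of 31 genes), with medians of 0.76 and 0.41 (27 and 21 genes adjusted over the list alone). Of 26 ribosome biogenesis genes 22 were positive and 1 negative in ER3, and 17 and 1 in T15-2 (20 positive adjusted over the list alone). Of 18 FOXO targets 9 had a negative difference and 1 a positive one in each subline (11 and 2 in ER3 and 12 and 1 in T15-2 adjusted over the list alone). These 4 lists were also called with an estimated correlation, at adjusted p of 0.0034 or lower. In all, 2602 genes differed in ER3 (1372 positive, 1230 negative) and 1545 in T15-2 (848 positive, 697 negative). After median scaling 1227 were positive and 1561 negative in ER3, and 810 and 819 in T15-2, so the balance of the directions depends on the scaling. The median difference of all genes in ER3 was then -0.11, and the differences named here exceed it in size. Without T15-2 erlotinib replicate 2 the T15-2 count was 955.

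**Figure D2:**
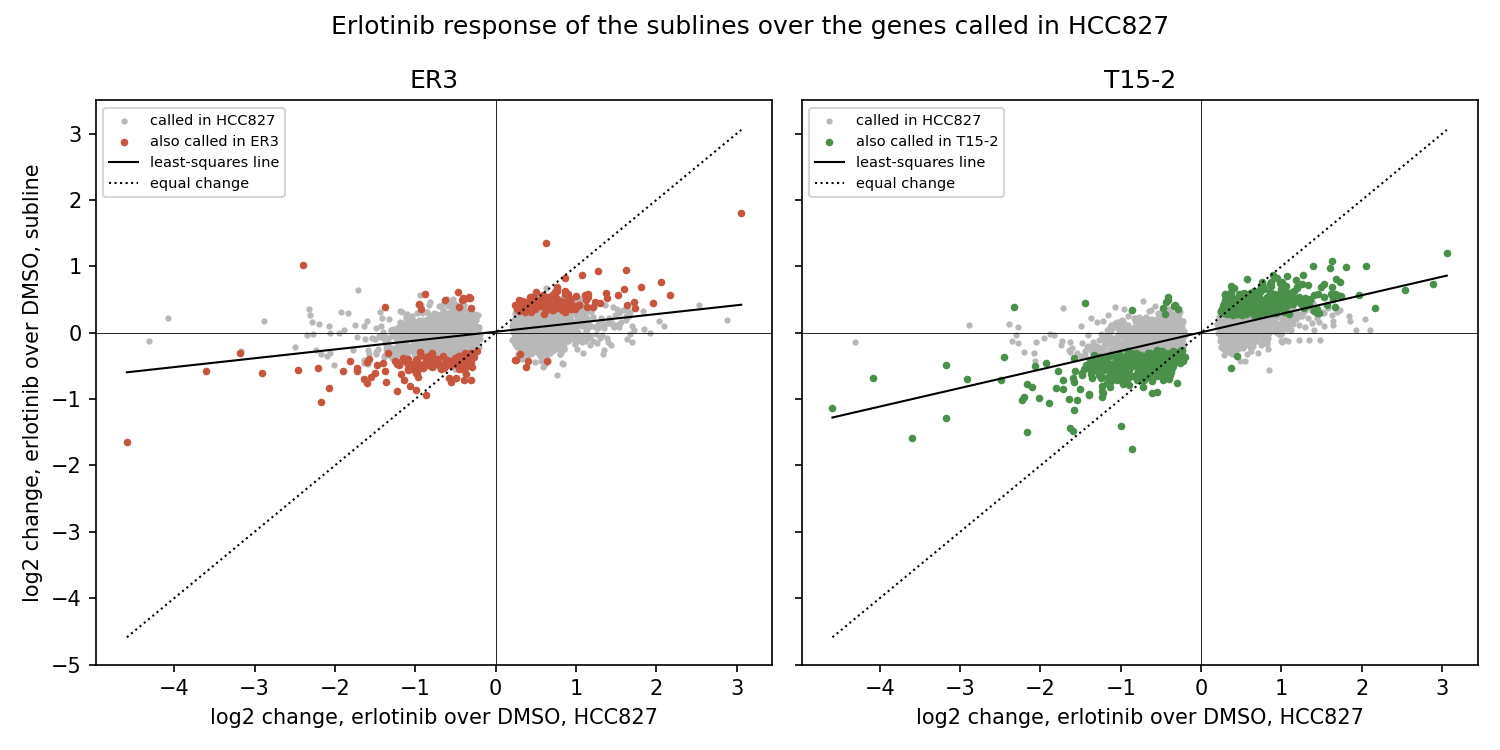
Log2 change with erlotinib in HCC827 (horizontal axis) against that in ER3 (left) and T15-2 (right, both vertical axes log2) for the 4458 genes called in HCC827; each point is a gene and coloured points were also called in the subline. The solid least-squares line has a slope of 0.13 in ER3 and 0.28 in T15-2, below the dotted line of equal change.

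The overlap of the responses was counted next. Of the 4458 genes called in HCC827, 253 were called in the same direction in ER3 (124 higher, 129 lower) against 83.8 for independent lists, and 21 in the opposite direction. In T15-2, 761 were called in the same direction (372 higher, 389 lower) against 188.2 for independent lists, and 13 in the opposite direction. FGFBP1, HSPA1A, CYP1A1, YPEL3 and KLHL24 are among the genes called the same way in all 3 lines. PTGS2 is among the 21 opposite genes of ER3, and CCN2, which encodes a matricellular growth factor, and SGPP2 among the 13 of T15-2. Over the genes called in HCC827, the slope of the subline's change on that of HCC827 was 0.13 in ER3 and 0.28 in T15-2, a description across genes, which are not independent replicates. The ER3 overlap was 11 with each line fitted alone and 84, 151 and 109 without ER3 DMSO replicate 1, ER3 DMSO replicate 3 and ER3 erlotinib replicate 1. The T15-2 overlap was 431, 485 and 499 without T15-2 DMSO replicate 1, 2 and 3, and 377 and 441 without T15-2 erlotinib replicate 1 and 2.

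ER3 was next compared with HCC827 in DMSO, to find what separates this subline from its parent without the drug. AXL, a receptor tyrosine kinase, was higher in ER3 by 2.97 ± 0.17 (adjusted p = 1.1e-10), and its second probe gave 2.83. GAS6, the ligand of AXL, was higher by 1.23 ± 0.08, and ABCB1, a drug efflux pump, by 2.02 ± 0.14. The glucose transporter SLC2A3 rose by 3.13 ± 0.10, KLRC3 by 3.09 ± 0.10, NKD2 by 3.03 ± 0.09 and CST7 by 2.95 ± 0.11, and the cytidine deaminase APOBEC3G was at least 6.69-fold higher. LUM, which encodes the proteoglycan lumican, rose by 3.90 ± 0.12, whereas a second LUM probe gave 0.36. VCAN, which encodes versican, was at least 12.1-fold lower in ER3, and PGM5 and IRX5 at least 11.6-fold and 9.75-fold lower. ADGRG2 changed by -3.90 ± 0.11, CD70 by -3.69 ± 0.12, KRT4 by -3.51 ± 0.11 and IGFBP2 by -3.09 ± 0.13; ADGRG2, CD70 and IGFBP2 were above background on 1 of 3 ER3 DMSO arrays. EGFR (0.18 ± 0.11, adjusted p = 0.21), MET (0.08 ± 0.23, adjusted p = 0.82) and ERBB3 (0.25 ± 0.13, adjusted p = 0.15) did not pass. EGFR had an adjusted p of 0.024 after median scaling (0.31) and of 0.026 with the array component as a covariate, chosen after seeing the data (0.26), and ERBB3 of 0.034 without ER3 DMSO replicate 2 (0.38), with or without T15-2 erlotinib replicate 3.

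**Figure D3:**
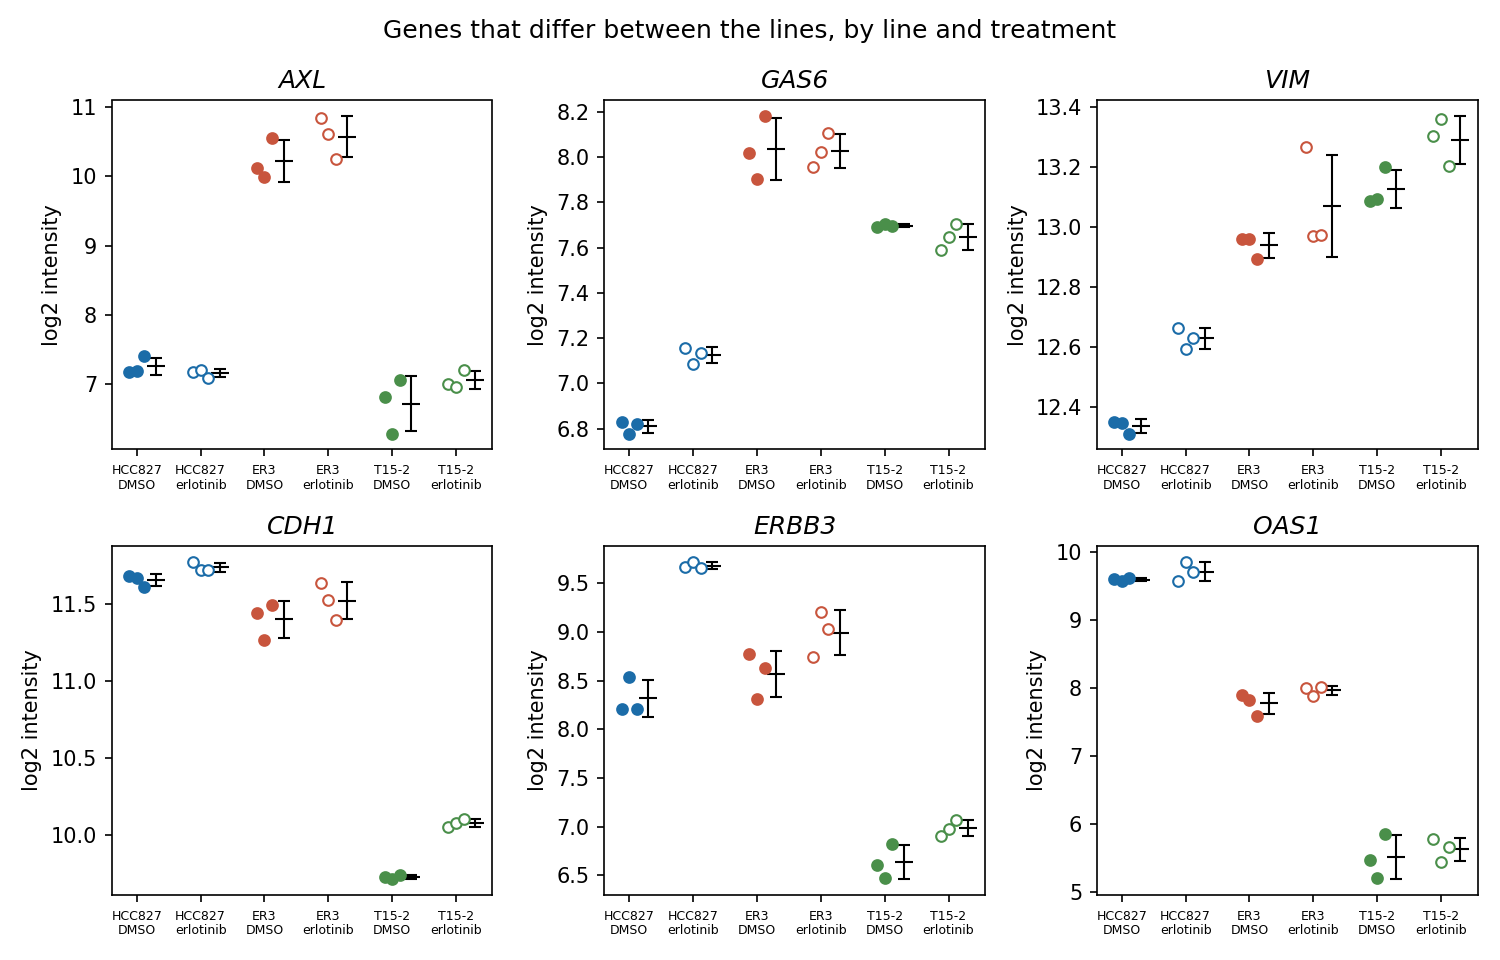
Log2 intensity (vertical axis, quantile-normalized) of AXL, GAS6, VIM, CDH1, ERBB3 and OAS1 on each of the 18 arrays, by line and treatment (horizontal axis). Filled points are DMSO arrays, open points erlotinib arrays, and bars are mean ± SD (n = 3). AXL in DMSO is higher in ER3 than in HCC827 by 2.97 log2 units, and CDH1 and OAS1 change by -1.92 and -4.09 in T15-2.

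Of 22 genes of MAPK pathway output, 14 were higher and none lower in ER3 (15 adjusted over the list alone), with DUSP5 at 2.00 ± 0.12, EPHA2 at 1.30 ± 0.12 and FOSL1 at 1.16 ± 0.13. DUSP6, of the same list, did not pass (-0.43 ± 0.20, adjusted p = 0.10), but was called lower without ER3 DMSO replicate 2 (-0.72, adjusted p = 0.0021). With settings chosen after seeing the data its adjusted p was 0.00091 without that array and T15-2 erlotinib replicate 3 (-0.72), and 0.016 with the centred array component as a covariate. Of 23 mesenchymal markers 12 rose and 2 fell, with N-cadherin (CDH2) at 1.39 ± 0.08, the repressor SNAI2 at 1.14 ± 0.12 and vimentin (VIM) at 0.60 ± 0.09. The epithelial list was not called (4 rose and 7 fell of 36, camera adjusted p = 0.90). E-cadherin (CDH1) changed by -0.25 ± 0.08 (adjusted p = 0.023), a call lost after median scaling (-0.19, adjusted p = 0.068) and in a fit of the compared groups alone (adjusted p = 0.077). Its adjusted p was also 0.068, 0.060 and 0.11 without HCC827 DMSO replicate 1, HCC827 DMSO replicate 2 and ER3 DMSO replicate 2, and 0.10 without the latter and T15-2 erlotinib replicate 3. Of 18 YAP and TEAD targets 7 rose and 1 fell, with NT5E and CCN1 both at 1.23 (SE 0.10 and 0.11) and ANKRD1 at 1.17 ± 0.14. The DNA replication list was lower (26 of 31 fell, none rose; 27 fell adjusted over the list alone), with GINS2 at -1.33 ± 0.10 and FEN1 at -1.01 ± 0.10. PCNA, the replication clamp, fell by 1.00 ± 0.11 on the log2 scale, and 10 of 12 heat shock genes fell. Of 13 genes of lung epithelial differentiation 11 fell and 1 rose. The surfactant protein gene SFTPB changed by -2.35 ± 0.13 and HOPX by -1.96 ± 0.14, while FOXA2, a lung transcription factor, rose by 1.80 ± 0.09. Of 30 interferon response and MHC class I genes 21 fell and 5 rose (22 fell adjusted over the list alone), with IFI27 at -2.31 ± 0.15 and OAS2 at -2.10 ± 0.10. Of 21 glycolysis genes 12 rose and none fell (14 rose adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.067 with an estimated correlation). The fibroblast, leukocyte and endothelial lists, which could mark other cells in the sample, were not called (camera adjusted p = 0.17, 0.75 and 0.87).

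Between ER3 and HCC827, 4145 genes passed, 1895 higher and 2250 lower in ER3, and 355 changed by at least 2-fold. After median scaling 2500 were higher and 1875 lower, so the balance of the directions depends on the scaling. Of the 27 lists, 13 were called and 7 of these also with an estimated correlation.

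T15-2 differed from HCC827 by large falls of interferon-stimulated genes. OAS2 changed by -4.14 ± 0.10, IFI27 by -4.11 ± 0.15, OAS1 by -4.09 ± 0.13 and MX1 by -3.61 ± 0.10, and of 30 genes for interferon response and MHC class I 23 fell and none rose (25 fell adjusted over the list alone, median -1.11, camera adjusted p = 5.5e-21). Of 36 epithelial markers 25 fell and none rose (26 fell adjusted over the list alone), with CDH1 at -1.92 ± 0.08, the transcription factor OVOL2 at -2.36 ± 0.11, RAB25 at -2.32 ± 0.11 and MARVELD3 at -2.21 ± 0.10. CEACAM6, a cell adhesion molecule, changed by -3.82 ± 0.10, FGFBP1 by -3.71 ± 0.10 and HOPX by -3.61 ± 0.14, VCAN was at least 12.4-fold lower, and LAMP3 at least 8.47-fold. VGF, which encodes a secreted neuropeptide precursor, rose by 3.01 ± 0.10, DDIT4L by 2.74 ± 0.10, CST7 by 2.36 ± 0.11, KLRC3 by 2.15 ± 0.10 and SRPX by 2.03 ± 0.11. ABCB1 rose by 2.01 ± 0.14. RAB25 and MARVELD3 were above background on 2 of 3 T15-2 DMSO arrays, SRPX on 2 of 3 HCC827 DMSO arrays and DDIT4L on 1 of 3.

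Of 23 mesenchymal markers 11 rose and 3 fell in T15-2: CDH2 changed by 1.07 ± 0.08, VIM by 0.79 ± 0.09, ZEB2 (above background on 2 of 3 HCC827 DMSO arrays) by 0.78 ± 0.13 and S100A4 by -1.37 ± 0.15 (adjusted p of the list 0.035 with an estimated correlation). GAS6 rose by 0.89 ± 0.08. AXL changed by -0.54 ± 0.17 (adjusted p = 0.024), with adjusted p of 0.094 and 0.17 without HCC827 DMSO replicate 3 and T15-2 DMSO replicate 2. The receptor genes ERBB3 and ERBB2 changed by -1.68 ± 0.13 and -0.76 ± 0.16. EGFR changed by -0.51 ± 0.11 (adjusted p = 0.0014), a call lost with the mean of its probes (-0.20, adjusted p = 0.15). Of 13 genes of lung epithelial differentiation 9 fell and 2 rose, and SFTPB, above background on 2 of 3 T15-2 DMSO arrays, changed by -2.67 ± 0.13. Of 26 ribosome biogenesis genes 12 rose and 1 fell (13 rose adjusted over the list alone), with NOP16 at 0.89 ± 0.15, and MYC, of the MAPK list, rose by 0.93 ± 0.10. CDKN1A changed by -1.86 ± 0.11. Of 18 cholesterol genes 11 fell and 1 rose, and of 12 fatty acid synthesis genes 9 fell and none rose, with the acetyl-CoA synthetase ACSS2 at -1.64 ± 0.08. In all, 3811 genes passed, 1884 higher and 1927 lower in T15-2 (2064 and 1761 after median scaling), and 356 changed by at least 2-fold.

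The sublines were also compared with each other. AXL was lower in T15-2 than in ER3 by a log2 change of -3.50 ± 0.17 and LUM by -3.71 ± 0.12, a value its second probe (-0.30) does not show. PLAC8 changed by -3.52 ± 0.08, DNAAF11 by -3.44 ± 0.11 and the kinase gene MAPK13 by -2.70 ± 0.10, and APOBEC3G was at least 6.64-fold lower. PKIA, which encodes an inhibitor of protein kinase A, was higher in T15-2 by 2.43 ± 0.12, FLRT3 by 2.35 ± 0.08, RRAGD by 2.17 ± 0.12 and TSPAN8, above background on 1 of 3 ER3 DMSO arrays, by 2.09 ± 0.13. Of 36 epithelial markers 26 were lower and none higher in T15-2, with OVOL2 at -2.45 ± 0.11, CLDN7 at -1.93 ± 0.11 and CDH1 at -1.67 ± 0.08. Of 30 interferon and MHC class I genes 24 were lower and 1 higher (25 lower adjusted over the list alone). Of 31 DNA replication genes 23 were higher and none lower (27 higher adjusted over the list alone), with GINS2 at 1.18 ± 0.10, and of 26 ribosome biogenesis genes 13 were higher and 1 lower (14 and 2 adjusted over the list alone). The camera adjusted p of these 4 lists was 0.0041 or lower with an estimated correlation. VIM had a value of 0.19 ± 0.09 (adjusted p = 0.11), which passed after median scaling (0.24, adjusted p = 0.020) and with the mean of its probes (0.31, adjusted p = 0.0062). In all, 3947 genes passed, 2109 higher and 1838 lower in T15-2 (1756 and 1856 after median scaling), and 279 changed by at least 2-fold.

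**Figure D4:**
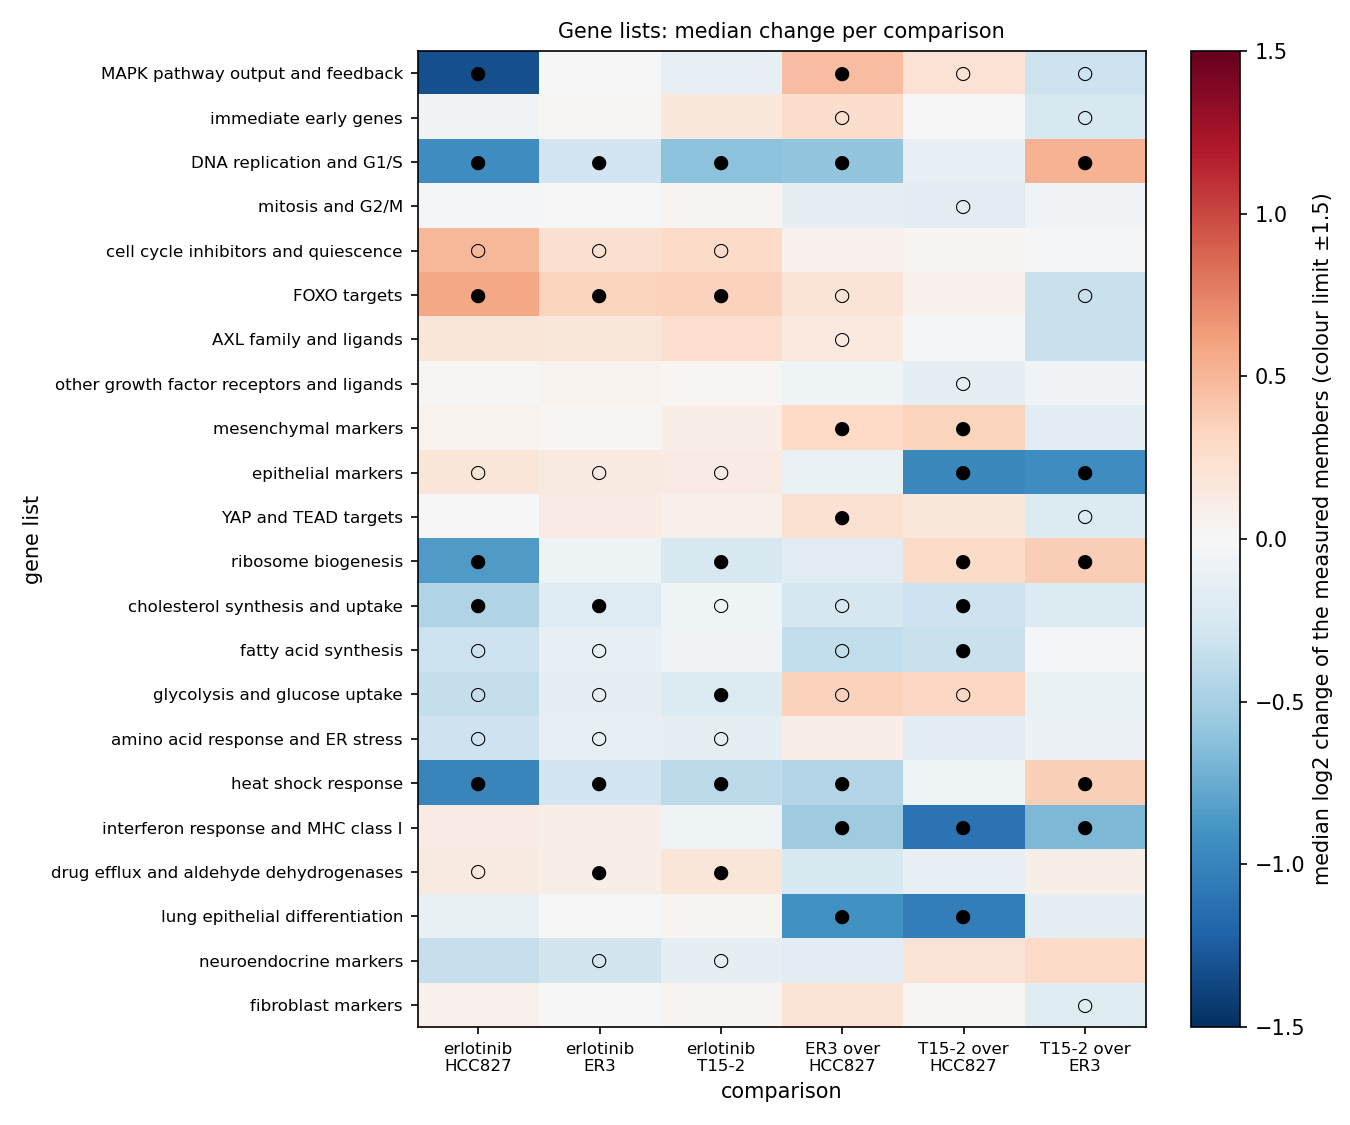
Median log2 change (colour, limits ±1.5) of the measured members of the 22 gene lists called by camera in at least 1 of 6 comparisons (rows, lists; columns, comparisons). Filled circles mark lists called by camera with the preset and the estimated correlation, open circles lists called with the preset one alone. The MAPK list has a median of -1.31 in HCC827 with erlotinib and is not called in ER3 or T15-2 with erlotinib.

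What ER3 and T15-2 shared against HCC827 was counted last. VCAN and SFTPB were lower and ABCB1, GAS6, CDH2, CST7, KLRC3 and SLC2A3 higher in both. In all, 1836 genes were called in the same direction (802 higher, 1034 lower) against 668.9 for independent lists, and 205 in opposite directions. Both comparisons used the same 3 HCC827 DMSO arrays. In 20 simulations of unchanged groups against shared controls the mean number of such genes was 0, as groups without effects hardly allow otherwise. The log2 changes correlated at 0.586 in the data and 0.502 in the simulations, and their covariance was 0.110 and 0.0078. The simulated correlation arises from the shared controls by itself, whatever their spread, so the covariance is the better guide. It exceeded the simulated one by 0.102, so the spread between the control arrays accounts for little of it. A deviation common to all 3 control arrays would enter both comparisons and was not simulated, and too few control arrays were at hand to split them. A part of the excess of calls, of unknown size, may therefore still come from the shared controls.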

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

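The tests for untreated cells, for other cell types and with the array component were chosen or put in their present form after the results they address had been seen; those of the signal range and of other splits were set before, but the splits for the differences of response took their present form after 2 other forms had been counted. The difference of the erlotinib response between lines stood out for 2602 genes in ER3 and 1545 in T15-2. PTGS2 was singled out as the gene with opposite responses and the largest difference, 3.42 between ER3 and HCC827. Among 4172 kept probes without a single gene symbol, which the comparisons above leave out, 707 were called between ER3 and HCC827 and 584 between T15-2 and HCC827 in DMSO.

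The first pattern weighed is the smaller response of ER3 and T15-2 to erlotinib. With untreated cells on the subline arrays labelled erlotinib, genes of the HCC827 response would be called about as often in either direction. In ER3 253 were called the same way and 21 the opposite way, and in T15-2 761 and 13, which argues against untreated cells. The same-way calls also exceeded those of independent lists (83.8 and 188.2). That excess alone does not decide, since the lines share an estimate of the spread per gene, which can raise overlaps by itself. A compressed signal range on the subline arrays is argued against by the spread of log2 signals before normalization, whose ratio of sublines to HCC827 was 1.01. The first component of the spread within groups held 24.5% of that variance, with ER3 DMSO replicate 2 (15.6) and T15-2 erlotinib replicate 3 (-13.7) at its ends; with the array score of whole profiles as a covariate the median MAPK difference was 1.40 in ER3 (1.27 without it) and 1.34 in T15-2 (1.29 without it). These medians bear on the MAPK list alone. With the same covariate 1831 genes differed from HCC827 in ER3 (2602 without it) and 1058 in T15-2 (1545 without it). Whether the component adds to the number of differing genes thus stays open. A first form of that covariate, centred within groups, was void here, since it cannot move a difference between groups. A biological difference of the sublines, the study's own factor, remains a hypothesis here, and neither the growth state of the cultures nor the uptake of the drug was measured.

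The second pattern is the set of 444 genes called with erlotinib in ER3. That count was 132 without ER3 DMSO replicate 1 and 150 without ER3 erlotinib replicate 1. It was 14 in a fit of the ER3 arrays alone. A component learned from the HCC827 and T15-2 arrays, used as a covariate, left 451 calls, 362 of them called in the same direction without it, and the median change of the DNA replication list was -0.32 with it and -0.29 without it. The covariate also takes up spread within groups, which can raise counts. The number of calls thus does not decide whether that component is their source. The median change is free of this and argues against that component as the source of the DNA replication shift. Without ER3 DMSO replicate 2, which has the largest score on the first component over all arrays, 586 genes were called. How many of the 444 genes are among them was not counted. A component particular to the ER3 arrays was not tested and stays open.

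The third pattern is the rise of LUM, APOBEC3G, CST7 and KLRC3 in ER3, genes otherwise known from fibroblasts or lymphocytes. Fibroblasts among the cells would bring other abundant transcripts, but the median change of 10 other fibroblast markers was 0.053, 0 of them rose, and COL1A2 and COL3A1 were above background on 0 of 3 ER3 DMSO arrays. The median change of 11 leukocyte markers was -0.026, 1 of them rose (CD68, 0.39), and PTPRC was above background on 0 arrays. Signal from related transcripts was not tested, and the second LUM probe (0.36) leaves that gene's rise uncertain. CST7 and KLRC3 rose in T15-2 as well, where the markers of this paragraph were not tested in this way. The fibroblast list, LUM included, was called lower in T15-2 than in ER3 (median -0.18). That call was lost with an estimated correlation (camera adjusted p = 0.11). A change in ER3 itself remains open and was not tested further.

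With 3 arrays against 3 there are 10 splits, so no share under 0.05 can be reached for the 6 comparisons between 2 groups. In fits of the 6 arrays alone the real split, the 1 split with as many calls in each comparison, called 4849 genes for erlotinib in HCC827, 14 in ER3 and 720 in T15-2, and 3589, 4233 and 3335 for ER3 against HCC827, T15-2 against HCC827 and T15-2 against ER3; the highest other split called 0 in each. For the differences of response, the values were centred on the mean of each line and the line labels were split within each treatment, since equal responses would make these arrays exchangeable. Of the 200 splits, 100 were drawn with a fixed seed, the real one included. For ER3 only 1, the real split, gave as many as its 2350 genes (highest other 0). For T15-2 only 1, the real split, gave as many as its 1825 (highest other 994). This argues against equal responses of all genes in each subline and HCC827, within the limits of triplicates whose independence is unknown. It does not bear on how many genes differ, and an effect of the culture of each group is not excluded. The 2 earlier forms split the treatment labels within each line, and 3 and 4 of 100 splits for ER3 and 4 and 8 of 100 for T15-2 gave as many. They were void, since a subline with mixed labels has no response left and its difference from HCC827 stays large.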

How the results depend on the processing

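Alternatives were listed before the data were examined, except the array component as a covariate, in 2 forms, and the fit without both extreme arrays, which were chosen after seeing the data. No called result reversed; the median of the NF-kB list in the T15-2 difference was -0.06 after median scaling and 0.12 otherwise, with its call lost. Of 256 values of named genes 230, and of 83 list calls 47, kept their side of the threshold under all alternatives listed before; 35 list calls were lost with an estimated correlation, which left 48. Median scaling changed the balance of directions, with 141 genes higher and 228 lower for erlotinib in ER3, against 238 and 206 in the main fit. The total counts of calls stayed within 1.5 times under no background correction, median scaling, the authors' values, both filters and the mean of probes. They did so too under trend and robust settings and with the array component of whole profiles as a covariate. That form was chosen after the first form, with scores centred within groups, had given 995 and 1649 calls for erlotinib in ER3 and T15-2, 2363 for the T15-2 difference, and overlaps of 487 for HCC827 with ER3, 1142 for HCC827 with T15-2 and 475 for the sublines' erlotinib genes. By construction the first form removes spread within groups and leaves each difference as it was. With a 2-fold minimum, by construction fewer genes were counted: 376, 6 and 17 for erlotinib in HCC827, ER3 and T15-2, 355, 356 and 279 for ER3 and T15-2 against HCC827 and T15-2 against ER3, 297 and 168 for the differences of response of ER3 and T15-2, and 3, 15, 151 and 3 for the overlaps of HCC827 with ER3, of HCC827 with T15-2, of the sublines against HCC827 and of the sublines' erlotinib genes. With the compared groups alone, where fewer arrays estimate the spread, 14 genes were called for erlotinib in ER3, 11 overlapped between HCC827 and ER3 and 11 between ER3 and T15-2. Without both extreme arrays there were 840 calls for erlotinib in ER3, 2393 for the T15-2 difference and 377 in the overlap of the sublines' erlotinib genes; the cause was not tested. Without 1 array in turn, erlotinib in ER3 gave 132 to 586 calls, erlotinib in T15-2 441 to 1147 and the T15-2 difference 955 to 2023. The overlaps were 84 to 262 for HCC827 with ER3, 377 to 725 for HCC827 with T15-2 and 79 to 257 for the sublines' erlotinib genes; a group left with 2 arrays has less power, and the cause was otherwise not tested. The lowest counts came without ER3 DMSO replicate 1 and T15-2 erlotinib replicate 1 or 2.

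The replicate numbers did not pair the arrays: deviations of same-numbered arrays from their group means correlated between -0.40 and 0.098, and not every array correlated best with its own number in any comparison. With the replicate number as a block, 4342, 336 and 811 genes were called for erlotinib in HCC827, ER3 and T15-2, 4006, 3677 and 3790 between lines, and 2419 and 1388 for the differences of response. The blocked overlaps were 194, 629, 1769 and 168, and 82 list calls were made. The BeadChip as a block was not run, for lack of chip labels. Signal over background limits the dim genes, whose folds are bounds or are drawn toward 0.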

Other observations

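The histone genes, the overlap of the subline responses with its test, and the genes named within neighbour runs were chosen after their values had been seen, while the test of neighbours was set before. Of 44 measured histone genes 20 rose and 2 fell in HCC827 with erlotinib, where most of the DNA replication list fell, and the others were not called. Their median change was 0.36 (camera p = 5.3e-07 for this group alone, and 0.0063 with an estimated correlation). H4C14 rose by 1.63 ± 0.11, H2AC6 by 1.41 ± 0.13, H2AC18 by 1.39 ± 0.15 and H2BC5 by 1.35 ± 0.10, each with n = 3 per group. In T15-2 3 rose, and in ER3 none was called (median -0.01). The response was lower than in HCC827, whose arrays both differences share, for 18 of them in ER3 and 15 in T15-2. It was higher for 1 in ER3 and 0 in T15-2. The array shows no transcript ends, so polyadenylated and other histone transcripts cannot be separated here.

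The erlotinib responses of ER3 and T15-2 shared 222 genes called in the same direction (111 higher, 111 lower) against 18.8 for independent lists, and 0 were called in opposite directions, where the lines share no arrays. With the score on the first component of the within-group spread as a covariate the overlap was 285. That covariate also takes up spread within groups, which can raise counts, so 285 does not decide whether the component is the source of the overlap. A first form of the covariate, centred within groups, takes up the same spread and gave 475. It decides nothing either, since it leaves the changes as they were. The count was 11 with each line fitted alone, 79, 138 and 99 without ER3 DMSO replicate 1, ER3 DMSO replicate 3 and ER3 erlotinib replicate 1, and 139, 142 and 143 without T15-2 DMSO replicate 1, T15-2 erlotinib replicate 1 and T15-2 erlotinib replicate 2.

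A hypothesis was that neighbouring genes share shifts in the sublines, as gains or losses of chromosome parts would give. Genes were put in the order of assembly GRCh38.p14, and medians were taken over 31 neighbours at a time, in 11118 windows. In ER3 250 windows and in T15-2 257 lay beyond every window of 200 shuffled orders, against 7 in the erlotinib response of HCC827. Adjacent windows share most of their genes and join into runs, so these are not counts of separate regions. Such runs would arise from copy number differences between the lines, but no DNA was measured. In T15-2 85 genes from MRPL39 to ICOSLG had a median of -0.35, with 47 lower and 4 higher. This run holds the interferon receptor genes IFNAR2 (-0.93 ± 0.08), IFNGR2 (-0.69 ± 0.09) and IFNAR1 (-0.53 ± 0.10), and MX1 (-3.61 ± 0.10). In ER3, where the median of this run was -0.06, the 4 genes were called lower too (-0.24, -0.29, -0.38 and -1.82). Their falls thus also occurred without a shift of the whole run. Each was larger in T15-2, so a part that comes from the run is not excluded there. A run of 242 genes from ASL to TPI1P2, which holds ABCB1, CDK6 (1.33 ± 0.11) and MET (0.32 ± 0.23, adjusted p = 0.30), had a median of 0.36 in T15-2, and the 66 genes from TRIM56 to AASS, which hold MET (0.08 ± 0.23, adjusted p = 0.82), a median of 0.43 in ER3. MET was called in neither by the fit over 18 arrays, but in T15-2 with the array component as a covariate, chosen after seeing the data (0.55, adjusted p = 0.025). ABCB1 rose by 2.01 in T15-2, above the median of its run. It rose by 2.02 in ER3, where the runs found do not hold it but the same 242 genes had a median of 0.27. In ER3 CDK6 rose too (0.88 ± 0.11), while ABCB4 did not pass (0.22 ± 0.10, adjusted p = 0.082). A further ER3 run of 59 genes, from RABGEF1 to DMTF1, had a median of 0.35, with 28 higher and 0 lower. How near that run lies to ABCB1 was not examined, so a shift of the stretch around ABCB1 in ER3 is not excluded. The 7 windows of the HCC827 response lay in 2 runs, from H4C14 to SELENBP1 and from C6orf62 to PRSS16, which hold histone genes.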
